A study of Homo sapiens
Mus musculus with 14 samples.

How the data were processed

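Single cell transcript counts came from 14 xenograft samples: 2 subcutaneous tumors each of SW480-CBC, SW480-RSC and parental SW480, and 4 orthotopic samples each of CBC and RSC. Per the labels, each subcutaneous sample was 1 tumor and each orthotopic sample pooled the tumors of 1 cecum, and libraries were made with 3' reagents of version 3 from cells sorted for the absence of a viability dye. Hyaluronidase was added to the dissociation of orthotopic tumors only. The deposited matrices hold raw integer UMI counts per gene and barcode from Cell Ranger 3.1.0, per the file headers, on a joint reference of the human build GRCh38 and the mouse build mm10, per the labels. The same labels list R 3.6.1 and Seurat 3.1.0 for the authors' later work, whose compiled objects were not among the files used here. The annotation release is not given in the sources used here. The mouse numbers in the sample names placed the CBC and RSC subcutaneous tumors of the same number on the 2 flanks of 1 mouse, both parental tumors in another mouse, and the orthotopic samples in 8 mice.

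A barcode was called human or mouse when at least 80% of its UMIs came from that species, and mixed otherwise. Cells were kept with at most 20% mitochondrial UMIs and at least 500 genes (human) or 200 genes (mouse). Files held 155442079 to 163502015 UMIs in parental, 137557568 to 207599978 in CBC subcutaneous, 132166002 to 156230048 in RSC subcutaneous, 63163698 to 93031571 in CBC orthotopic and 113685778 to 149513796 in RSC orthotopic samples. The limit on mitochondrial UMIs removed 25.2% to 63.3% of the human barcodes of orthotopic samples and 6.02% to 15.6% of those of subcutaneous tumors. Mouse UMIs made up 2.58% to 3.44% of the UMIs in orthotopic human cells and 0.131% to 1.12% in subcutaneous ones. No correction for free RNA was made.

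The 26651 mouse cells were scaled to 10000 UMIs, log-transformed and reduced to 2000 variable genes seen in at least 10 cells and 30 principal components, and 15 neighbours entered Leiden clustering at resolution 1.0 (seed 1). Each of the 37 clusters took the class with the most fixed markers that were detected in at least 25% of its cells and at least 2-fold higher than elsewhere, with a pseudocount of 0.1 per 10000. At least 3 markers were needed, and a cluster stayed unnamed where another class had 3 or more and at least 40% as many, where its top 10 genes held more markers of another class, or where it was low in UMIs with no own marker in its top 10. Classes are named "-like" because they rest on markers alone. With genes ranked by pooled counts, clusters 10 and 27 (epithelial) had mesothelial, cluster 29 (epithelial) had neutrophil and cluster 13 (fibroblast) had glial markers ahead of their own, so these 4 names are uncertain. Scrublet, expected to find 6%, called 115 cells (0.43%), so it did not work as a doublet filter here.

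UMIs were summed per sample over the cells of a class with at least 20 cells in that sample. The sums were compared with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F-test) and Benjamini-Hochberg adjustment at 0.05 in R 4.3.3. Orthotopic samples were fitted by group, the 6 subcutaneous samples as 3 groups, and the 12 CBC and RSC samples as 4 groups for the site comparison and the interaction. Standard errors were the absolute log2 fold change over the square root of F, and CPM values are means and SDs on TMM-scaled libraries. For genes with few UMIs in a group, standard errors made in this way can understate the error of counting. Where a group held 0 UMIs, a bound was given with 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval. Where leaving out a replicate left 1 sample in a group, that sample was assumed to vary like the other groups.

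Gene lists and markers were fixed before the data were examined, and were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The 15 human lists were crypt base stem cell, Wnt target, regenerative or fetal, YAP and TEAD target, mesenchymal, epithelial, cytokine, complement, protease and laminin, hypoxia and glycolysis, interferon, class I antigen presentation, cell cycle, dissociation stress, and stroma and blood genes. The 17 mouse lists were contractile fibroblast, inflammatory fibroblast, collagen and matrix, Wnt and BMP, complement, class II, interferon, inflammatory, alternative and lipid-associated macrophage, immature and tumor-conditioned neutrophil, endothelial tip, endothelial adhesion, hypoxia, cell cycle and dissociation stress genes. Named genes were chosen by rule. First came the 10 rising and 10 falling genes (6 and 6 in a mouse class) with the largest called change, an average log2 CPM of at least 5 and groups that did not overlap. To these were added up to 4 called members per list with the smallest adjusted p, or up to 2 of the highest expression where none was called, and always LGR5, ASCL2, AXIN2, ANXA1, CLU and CTGF in human cells. Mcpt1, Mcpt2 and Pthlh in orthotopic fibroblasts and Cyp2c55, Aqp8, Mcpt1, Mcpt2 and Car1 in orthotopic macrophages lay outside that rule and were chosen after their values were seen.

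Shares of 12 kinds of cells were compared in orthotopic samples with an exact permutation test over 70 splits, whose smallest p is 0.0286. For the position of single cells, each human cell of a subcutaneous tumor was thinned to 2000 UMIs and the multinomial likelihoods under the summed orthotopic RSC and CBC profiles (pseudocount 0.5 UMIs) were compared over the 4784 genes called there with at least 1 log2 unit.

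Same-numbered subcutaneous CBC and RSC tumors count as pairs because they share a mouse, and the deviations of their human sums from the group means correlated at 0.409. With 2 tumors per group this value sets 1 replicate difference against another, so it does not test for an effect of the mouse. The main fits left the pairing out, and it entered only as a block in an alternative. The alternatives tried were RLE size factors, DESeq2 1.42.0, no filter on counts, a fit over both sites, the replicate as a block, a species limit of 90%, a mitochondrial limit of 10%, minimums of 1000 and 500 genes, Leiden resolutions of 0.5 and 2.0, Scrublet removal, and shares among mouse cells without epithelial ones. Further ones were profiles without a fold minimum, thinning to 1000 UMIs, and leaving out each library. Chosen after seeing the data were fibroblasts without C1q UMIs, a mitochondrial limit of 50% and cells not thinned. Tested on simulated data with planted changes, the fits between 2 groups recovered 22% to 83% of 2-fold and 87% to 98% of 4-fold changes, with 1.55% to 5.52% false calls. The interaction and the site comparison were not simulated. Few genes were changed, as many up as down, whereas 71.7% of the genes were called between human RSC and CBC cells in the cecum. How the fits do with that many changes was not tested. Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 did the rest. Mixed barcodes and barcodes over the mitochondrial limit were not analysed here, except for the limit of 50%.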

Results

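Transcripts were counted cell by cell in 14 xenograft samples of SW480, a human colorectal adenocarcinoma line, grown in immunodeficient NSG mice. The tumors came from parental SW480 or from 1 of its 2 sub-lines, which the labels call CBC and RSC and the series title describes as cancer stem cell subtypes. Flank tumors were taken after 21 days, with 2 tumors each of CBC, RSC and parental cells. Tumors of the cecum wall were taken after 28 days from 4 CBC and 4 RSC mice, and the tumors of 1 cecum were pooled. Each file held 6736 to 15182 barcodes and 63163698 to 207599978 UMIs. After filtering, 5565 to 8941 human cells per subcutaneous tumor and 475 to 2862 per orthotopic sample remained. Mouse cells numbered 353 to 1503 per subcutaneous tumor and 1787 to 3938 per orthotopic sample. In RSC subcutaneous replicate 1, 24.3% of the barcodes mixed both species and the median human cell held 5882 UMIs. The other 13 samples had 0.668% to 6.67% mixed barcodes, and the other subcutaneous tumors had medians of 18139 to 21185 UMIs per human cell.

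The orthotopic tumors address how human cells of the RSC and CBC lines differ in the cecum (mean ± SD of CPM, n = 4 per group). MIA, a small secreted protein first found in melanoma cultures, stood at 426 ± 49.8 CPM in RSC against 0.133 ± 0.0546 CPM in CBC tumors. Its log2 fold change was 11.65 ± 0.20 (SE). For genes this near 0 in a group, the SE can understate the error of counting, here and below. The interferon-induced membrane protein IFITM3 stood at 1252 ± 163 against 2.48 ± 0.734 CPM, and CD74, the class II invariant chain, at 361 ± 76.0 against 0.427 ± 0.257 CPM. Among the other genes that rose were SHH, a hedgehog ligand (log2 fold change 8.10 ± 0.21), and the transglutaminase TGM2 (7.04 ± 0.33). IFITM1 gave 9766 UMIs in RSC and 1 in CBC tumors, a depth-corrected ratio of 5512 (95% counting interval 989 to 217732). The metallothionein MT1A gave a ratio of 1394 (477 to 6762). LCN2, an iron-scavenging lipocalin, varied between RSC tumors (142 ± 102 CPM), as did PAEP (147 ± 116 CPM) and the calprotectin subunit S100A9 (68.7 ± 61.7 CPM), whose ratio was 1181 (404 to 5727). Human S100A9 did not come with mouse neutrophils, since the neutrophil-like droplets of each of these samples held at most 1 of its UMIs.

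CBC cells held transcripts that RSC cells nearly lacked. SEMA3D, a secreted guidance factor, gave 5382 UMIs in CBC and 2 in RSC tumors, a ratio of 4768 (95% counting interval 1319 to 39380). Its relative SEMA3A fell from 184 ± 12.8 to 1.09 ± 0.287 CPM (log2 fold change -7.41 ± 0.14), and the transcription factor gene DACH1 from 125 ± 13.3 to 0.576 ± 0.263 CPM (-7.57 ± 0.18). KLRC2, a natural killer receptor gene, fell from 185 ± 17.1 to 0.653 ± 0.209 CPM, and ASB4 from 80.5 ± 17.3 to 0.0919 ± 0.0758 CPM. Lower too were the Notch target HES5 (-6.68 ± 0.64), the EGF-family ligand EREG (-6.93 ± 0.43), DPYSL3 (-7.13 ± 0.19), DWORF (-8.23 ± 0.58) and the long non-coding AC104823.1 (-7.90 ± 0.21). In total, 5593 of 15185 tested genes were higher and 5298 lower in RSC cells by edgeR's quasi-likelihood test, 2709 and 2075 of them at least 2-fold. All samples of a group carried the same sub-line, so the spread is that between mice. The test compares these 2 lines and does not reach other lines of either subtype. The IFITM, metallothionein, KLRC and HLA genes have near-identical relatives, between which the counting could have split reads.

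**Figure D1:**
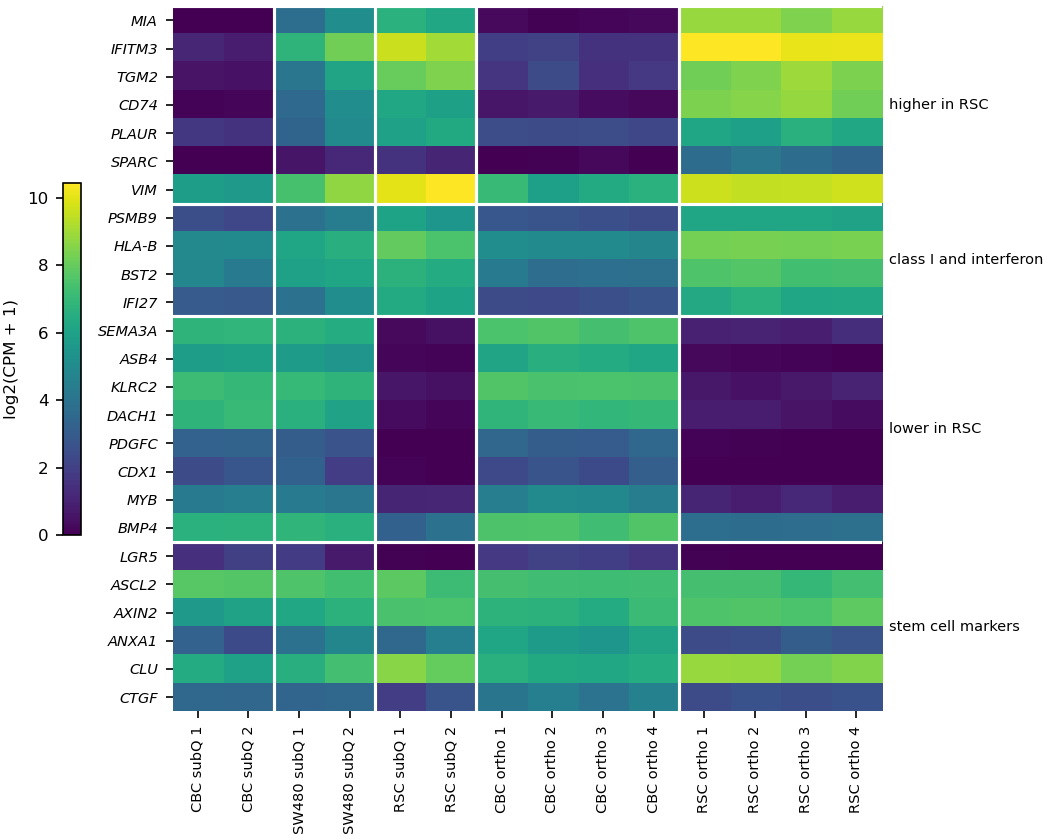
Human genes that differed between RSC and CBC tumors, as log2(CPM + 1) without TMM scaling, with 1 column per library and brighter cells higher. MIA and CD74 were dark in the CBC libraries at both sites, and SEMA3A, DACH1 and LGR5 were dark in the RSC libraries.

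Among the 6 genes followed in every human comparison, LGR5, a receptor that marks crypt base stem cells, was found as 182 UMIs in orthotopic CBC and 1 in RSC cells, a ratio of 322 (95% counting interval 57.2 to 12806). ASCL2, a stem cell transcription factor, stood at 151 ± 17.5 CPM in RSC and 155 ± 11.6 CPM in CBC tumors (log2 fold change -0.04 ± 0.10, adjusted p = 0.754). AXIN2, a feedback inhibitor of Wnt signalling, rose to 197 ± 17.1 from 109 ± 13.8 CPM, and the secreted chaperone CLU rose to 389 ± 71.6 from 87.0 ± 5.94 CPM. The regenerative marker ANXA1 fell by 3.46 on the log2 scale, and the YAP target CTGF fell from 18.9 ± 3.61 to 4.83 ± 0.369 CPM. Of the crypt base stem cell list, 6 of 10 measured members fell, with MYB (-4.79 ± 0.23) and the chloride cotransporter SLC12A2 (-2.78 ± 0.10) among them, while EPHB2 rose (1.92 ± 0.11). Of the Wnt target list, 7 rose and 5 of 15 fell, the latter with BMP4 (-3.88 ± 0.09) and DKK1 (-3.56 ± 0.12); its median was 0.10, its mean -0.22 and its camera direction down. Of the regenerative or fetal list, 7 of 12 members rose, among them PLAUR (4.05 ± 0.17) and EMP1 (3.01 ± 0.14), and 2 fell. YAP and TEAD targets split into 13 higher, such as MYOF (2.41 ± 0.09), and 7 lower of 21, such as PTPN14 (-1.84 ± 0.09). With camera's preset correlation the stem cell list was lower (adjusted p = 0.0214), the regenerative list (0.00135) and the YAP list (0.0169) higher, and the Wnt list was not called (0.389). The adjusted p values were 0.251, 0.251, 0.343 and 0.698 with an estimated correlation, in the same order.

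Among immune and matrix genes of the orthotopic RSC cells, all 11 class I antigen presentation genes were higher, with the immunoproteasome gene PSMB9 (3.69 ± 0.11) and HLA-B (3.32 ± 0.11). Of 11 interferon response genes 10 rose, with IFI27 (4.09 ± 0.14) and BST2 (3.58 ± 0.13) among them. Complement genes and regulators counted 5 higher and 1 lower of 9, and C3, the central complement component, gave 730 UMIs against 1, a ratio of 412 (95% counting interval 73.7 to 16296). Of 11 proteases and laminins 10 were higher, including the laminin receptor ITGB4 (1.63 ± 0.11), and of 9 mesenchymal genes 5 were higher, including VIM (3.04 ± 0.18) and SPARC (6.97 ± 0.38). With the preset correlation, camera's adjusted p was 1.7e-11, 1.9e-06, 0.0263, 1.1e-04 and 0.00949 for these 5 lists. In the same order, adjusted p = 0.0998, 0.167, 0.23, 0.251 and 0.312 with an estimated correlation.

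Cytokine genes went both ways, with 9 higher and 9 lower of 21 (camera adjusted p = 0.636). The chemokine CXCL16 rose (3.30 ± 0.11), and PDGFC, a ligand of the PDGF receptors, fell (-7.71 ± 0.33). Epithelial genes counted 8 higher, such as CDH1 (1.91 ± 0.13), and 5 lower of 14, such as VIL1 (-1.38 ± 0.12), with a median of 0.60, a mean of -0.36 and an upward camera direction (adjusted p = 0.462). The intestinal transcription factor CDX1 had 0 UMIs in RSC cells and was at least 191-fold lower, with 3 counts over the group as the floor. Of 13 hypoxia and glycolysis genes 10 were higher, such as the peptide hormone ADM (2.77 ± 0.17), and 2 lower; 7 of 12 immediate-early and heat shock genes were higher, such as EGR1 (1.33 ± 0.11), and 1 lower. Of 15 cell cycle genes 11 were lower, such as the mitotic cyclin CCNB1 (-1.02 ± 0.09) and CCNA2 (-1.31 ± 0.11), and 1 higher. Camera's adjusted p was 0.0214, 0.0319 and 0.0284 for these 3 lists, and adjusted p = 0.45, 0.508 and 0.251 with an estimated correlation. Of the stroma and blood markers that other human cells would bring, 3 were measured: S100A9 was higher and LYZ, lysozyme, lower (-4.22 ± 0.19), with a median of -0.55, a mean of 1.85 and no call (camera adjusted p = 0.389). Adjusted over the list alone, the counts were the same in these lists except for 14 higher YAP and TEAD targets.

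In subcutaneous tumors the same lines differed by many of the same genes (mean ± SD of CPM, n = 2 per group). MIA gave 20287 UMIs in RSC against 3 in CBC cells, a ratio of 7601 (95% counting interval 2601 to 36863). IFITM3 rose from 1.06 ± 0.342 to 582 ± 153 CPM, TGM2 from 0.486 ± 0.0605 to 274 ± 62.8, the cytidine deaminase APOBEC3G from 1.06 ± 0.113 to 185 ± 13.1 and the protease inhibitor SERPINA1 from 2.52 ± 0.110 to 219 ± 0.612. Higher too were the calcium-binding S100A2 (log2 fold change 6.41 ± 0.69), the scaffold AKAP12 (6.35 ± 0.68), GPRC5A (6.06 ± 0.72), the chloride channel ANO1 (6.00 ± 0.54) and EMP1 (6.84 ± 0.79). On the CBC side were SEMA3C (-12.12 ± 0.90), SEMA3A (-8.85 ± 0.32), the glutamate receptor subunit GRIN2B (-10.57 ± 0.45), the trefoil peptide TFF3 (-9.22 ± 0.60), the granzyme gene GZMA (-8.57 ± 0.94) and SPANXD (-12.65 ± 0.63), a cancer-testis gene with near-identical copies. DACH1 (-9.65 ± 0.40), ASB4 (-9.41 ± 0.27), DWORF (-9.78 ± 0.59) and AC104823.1 (-10.89 ± 0.77) were lower in RSC cells here as in the cecum. LGR5 gave 691 UMIs in CBC and 3 in RSC cells, a ratio of 205 (69.8 to 996). AXIN2 rose (1.37 ± 0.19) and so did CLU (1.82 ± 0.32), and CTGF fell (-1.57 ± 0.31). ASCL2 (-0.47 ± 0.23, adjusted p = 0.136) and ANXA1 (1.01 ± 0.51, adjusted p = 0.138) did not pass. Of 19936 tested genes, 4810 were higher and 5079 lower, in a comparison where 1 of the 2 RSC tumors was the replicate with 24.3% mixed barcodes.

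By list, 13 of 14 regenerative or fetal genes and 13 of 21 YAP and TEAD targets were higher in subcutaneous RSC cells, the latter with the receptor AXL (5.90 ± 0.53) and IGFBP3 (5.28 ± 0.55), and 3 YAP targets were lower. The mesenchymal list had 8 higher members of 11, with VIM (4.25 ± 0.44) and the membrane protease MMP14 (3.77 ± 0.36), and 1 lower, ZEB2, whose ratio was 56.6 (95% counting interval 19.1 to 277). All 11 class I genes, PSMB8 (2.63 ± 0.17) among them, 8 of 12 interferon genes, IFITM1 (9.60 ± 0.70) among them, 10 of 12 proteases and laminins, with 1 lower, and 9 of 14 hypoxia genes rose. Of the stem cell list 5 of 11 fell, MYB (-4.35 ± 0.20) among them, and 2 rose. With the preset correlation camera called these 8 lists at adjusted p = 3.6e-07, 2.7e-05, 1.0e-03, 3.6e-07, 5.6e-04, 2.9e-04, 0.0152 and 0.0487, in the order named. In that order, adjusted p = 0.443, 0.532, 0.443, 0.443, 0.443, 0.443, 0.629 and 0.532 with an estimated correlation. The 7 lists without a call were Wnt targets (3 higher with AXIN2, 7 lower with BMP4 at -3.48 ± 0.27), cytokines (10 higher with LIF at 7.87 ± 0.87, 6 lower with PDGFC at -9.24 ± 0.40), complement (4 higher with C3 at 7.69 ± 0.89), epithelial genes, cell cycle genes, stress genes and stroma markers. Epithelial genes were 7 higher and 5 lower with a median of -0.33 against an upward camera direction. Of the cell cycle list RRM2 alone rose (1.24 ± 0.26), and 2 stress genes rose. The stroma markers S100A9 (8.94 ± 0.85) and COL1A1 rose, LYZ fell (-3.36 ± 0.56), COL1A2 was lower by a ratio of 208 (37.0 to 8257), and DCN was at least 21.4-fold lower. When adjusted over the list alone, 3 stem cell genes rose, 7 epithelial and 8 cytokine genes fell, 9 interferon genes rose and 1 fell, and 0 stress genes were called, with the other lists at the counts given.

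Between the sites, 7008 of the 15184 genes tested in both comparisons were called in both. Of these, 3608 were higher and 3322 lower in RSC cells at both sites, against 1456 and 1345 for independent lists, and 78 had opposite signs. Across all 15184 genes, which are not independent replicates, the log2 fold changes of the sites had a Pearson correlation of 0.919.

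**Figure D2:**
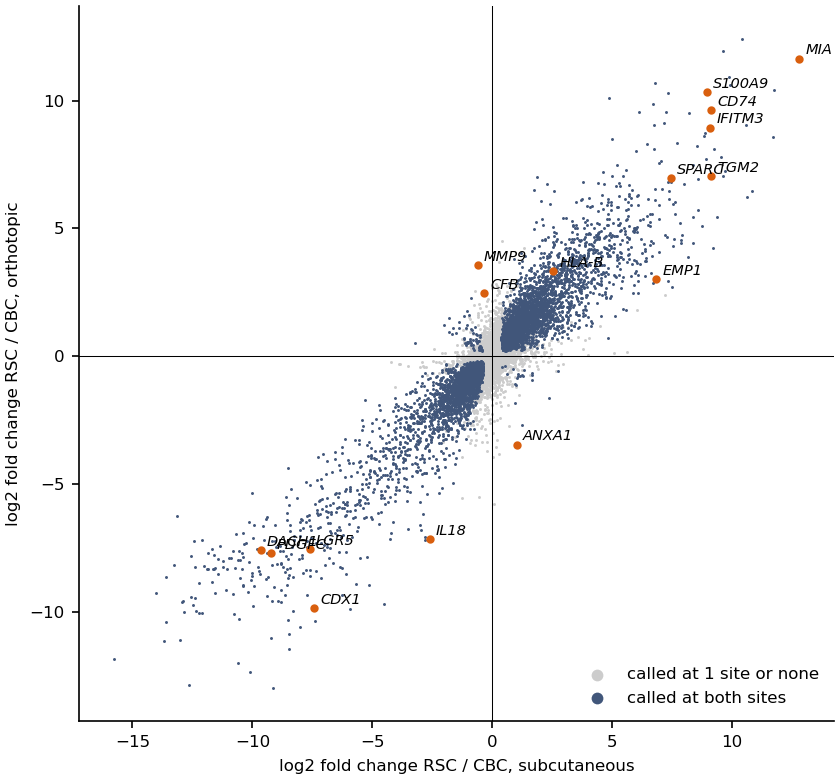
Log2 fold change of RSC over CBC human cells in orthotopic (vertical axis) against subcutaneous tumors (horizontal axis), with 1 point per gene tested at both sites. Genes called at both sites are dark, genes called at 1 site or none are grey, and 98.9% of the 7008 dark points lay in the lower left or upper right part.

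Whether the difference between the lines depended on the site was tested as an interaction, given here as the orthotopic minus the subcutaneous log2 difference of RSC from CBC. Site went together with the days of growth and with hyaluronidase, so a dependence on site cannot be separated from a dependence on them. The subcutaneous side held RSC replicate 1, with 24.3% mixed barcodes. The YAP pathway genes AJUBA (-2.32 ± 0.30), LATS2 (-2.25 ± 0.32), PTPN14 (-1.18 ± 0.17) and F3, tissue factor (-1.84 ± 0.25), the surface genes MSLN (-2.39 ± 0.25) and TM4SF1 (-2.04 ± 0.27) and ITGB4 (-1.86 ± 0.22) leaned less to RSC in the cecum. ANXA1 was lower in RSC cells in the cecum and higher, though not called, under the skin (-4.48 ± 0.57), and EMP1 rose less in the cecum (-3.84 ± 0.54). The inflammatory cytokine IL18 (-4.99 ± 0.97) leaned less to RSC in the cecum too. In the other direction lay the macrophage growth factor CSF1 (2.47 ± 0.44), the gelatinase MMP9 (4.16 ± 0.58), BST2 (1.81 ± 0.26) and B2M (1.23 ± 0.18). With them went the complement gene CFB (2.86 ± 0.68), the intestinal factor CDX2 (1.31 ± 0.20) and the Wnt genes NOTUM (1.51 ± 0.28), TNFRSF19 (1.13 ± 0.23) and RNF43 (1.00 ± 0.20). LGR5 (-0.45 ± 1.49), ASCL2 (0.41 ± 0.22), AXIN2 (-0.54 ± 0.19), CTGF (-0.41 ± 0.32) and CLU (0.33 ± 0.27) were not called, with adjusted p from 0.0826 to 0.904.

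By list, the interaction was negative for 12 of 21 YAP and TEAD targets, 6 of 13 regenerative genes, 5 of 15 cell cycle genes with RRM2 (-0.98 ± 0.24) and BIRC5 (-0.99 ± 0.25), 4 of 11 mesenchymal genes with VIM (-1.23 ± 0.30), and 5 of 23 cytokines. It was positive for 7 of 15 Wnt targets, 3 of 11 class I genes and 3 of 12 interferon genes. Camera called these 8 lists in those directions, with adjusted p from 1.4e-15 (YAP) to 0.00554 (cytokines). In the order named, adjusted p = 0.0572, 0.0705, 0.196, 0.0785, 0.287, 0.196, 0.253 and 0.246 with an estimated correlation. With calls adjusted over the list alone, the counts were 14, 9, 7, 6, 6, 10, 5 and 3. Median and mean had opposite signs for epithelial genes (0.05 and -0.41) and for proteases and laminins (-0.56 and 0.24), and the stem cell list had a median of -0.45 against an upward camera direction. In all, 893 genes had a positive and 737 a negative interaction of 17430 tested, and the total of 1630 dropped to 926 without RSC subcutaneous replicate 2. Calls that ended without 1 library were those of BIRC5 (CBC subcutaneous replicate 2 or RSC subcutaneous replicate 1; adjusted p over the alternatives 6.2e-04 to 0.097), VIM (CBC or RSC subcutaneous replicate 2; 3.6e-05 to 0.12), RRM2 (CBC subcutaneous replicate 2; 5.3e-04 to 0.1) and CFB (CBC subcutaneous replicate 1; 9.2e-05 to 0.052).

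Orthotopic and subcutaneous human cells were compared with the 2 sub-lines weighted equally (n = 8 against 4 samples). In the cecum the neutrophil-attracting chemokines CXCL2 (log2 fold change 4.26 ± 0.54), CXCL1 (3.64 ± 0.46) and CXCL3 (2.74 ± 0.31) were higher, with 10 of 23 cytokine genes. Higher too were the RNA-decay factor ZFP36, at 169 ± 47.2 against 46.3 ± 30.8 CPM, the cadherin FAT1 (1.44 ± 0.16), the ephrin receptor EPHA2 (1.10 ± 0.20), the tRNA exporter XPOT (0.92 ± 0.08) and the amino acid transporter SLC38A2 (0.93 ± 0.14). YAP and TEAD targets counted 13 higher of 21, with MYOF (1.29 ± 0.12) and LATS2 (1.08 ± 0.16), proteases and laminins 10 of 14, with MMP14 (1.30 ± 0.17), and regenerative genes 6 of 13, with EMP1 (2.21 ± 0.29). Glycolysis genes were lower: GAPDH stood at 3646 ± 560.1 CPM in the cecum and 9290 ± 1485 under the skin, LDHA at 849 ± 205 and 2152 ± 306, and PGK1 at 349.8 ± 66.8 and 812 ± 162. Of 13 hypoxia and glycolysis genes 8 fell, PDK1 (-1.11 ± 0.10) among them, and 1 rose. Of 15 cell cycle genes 9 fell, with TYMS (-0.88 ± 0.10) and CDK1 (-0.98 ± 0.18). The cytokine MIF (-0.85 ± 0.13), the mitochondrial MT-ND1 (-1.06 ± 0.11) and NRN1 (-1.88 ± 0.19) were lower as well. So was MTRNR2L8 (208 ± 49.6 against 585 ± 285 CPM), a nuclear copy of a mitochondrial gene whose reads can be shared. UMIs of MT-ND1 count toward the mitochondrial limit on cells. That limit removed more human barcodes in the cecum, so the fall of MT-ND1 cannot be separated from it.

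Camera called these 6 lists at adjusted p = 1.9e-05 (cytokines), 3.3e-06 (YAP), 6.0e-05 (proteases), 0.00656 (regenerative), 4.7e-06 (hypoxia) and 0.0106 (cell cycle), and the same counts held adjusted over the list alone except for 11 cytokine genes higher and 10 cell cycle genes lower. In that order, adjusted p = 0.2, 0.2, 0.2, 0.39, 0.224 and 0.55 with an estimated correlation. ASCL2 was lower (-0.57 ± 0.11) and its list partner SMOC2 too (-1.15 ± 0.28), while AXIN2 was higher (0.33 ± 0.10); CTGF (0.34 ± 0.16), ANXA1 (0.57 ± 0.28), LGR5 (-0.27 ± 0.76) and CLU (0.04 ± 0.13) were not called (adjusted p 0.0937 to 0.833). In total 3489 genes were higher and 4031 lower of 17430 tested, 396 and 590 of them at least 2-fold. Site went together with the days of growth and with hyaluronidase in the dissociation, so their effects cannot be separated. The mitochondrial limit removed 25.2% to 63.3% of the human barcodes in orthotopic and 6.02% to 15.6% in subcutaneous samples, and mouse UMIs made up 2.58% to 3.44% and 0.131% to 1.12% of the UMIs in human cells, so such quality differences go with the site as well. The calls of AXIN2 ended without CBC subcutaneous replicate 1 (adjusted p over the alternatives 0.0018 to 0.056), of SPARC (3.11 ± 0.69) without CBC orthotopic replicate 3 (1.5e-07 to 0.16), and of ZFP36 without RSC subcutaneous replicate 1 (3.3e-47 to 0.052).

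Parental SW480 tumors were set against both sub-lines under the skin (n = 2 tumors per group). The values are sums over all human cells of a tumor, and parental tumors mixed cells nearer RSC with cells nearer CBC, as scored below. The sums therefore do not show that single cells held both kinds of transcripts. Both parental tumors grew in the same mouse, which held no CBC or RSC tumor. The effect of the line therefore cannot be separated from that of the mouse in either parental comparison. They held much of the RSC expression that CBC cells lacked: MIA gave 6791 UMIs against 3 in CBC cells, a ratio of 2306 (95% counting interval 789 to 11184), and IFITM3 stood at 203 ± 125 against 1.06 ± 0.342 CPM. TGM2 (6.43 ± 0.71), EMP1 (5.47 ± 0.75), APOBEC3G (5.25 ± 0.56), SERPINA1 (5.17 ± 0.31) and the neuronal pentraxin NPTX2 (4.46 ± 0.46) were higher than in CBC cells. So were AXL (3.91 ± 0.49), the urokinase PLAU (4.34 ± 0.67), IFITM1 (7.73 ± 0.67) and PSMB8 (1.56 ± 0.16), with SPARC by a ratio of 129 (35.3 to 1069.8). The metallothionein MT3 (-1.63 ± 0.24), SPANXD (-2.71 ± 0.36) and the ribosomal protein genes RPS28 (-0.87 ± 0.14) and RPS27 (-0.87 ± 0.14) were lower. Of 21 YAP and TEAD targets 7 were higher, of 11 class I genes 6, and of 14 regenerative genes 5 (adjusted over the list alone, 13, 8 and 10). Camera called 11 of the 15 lists, each of them upward, these 3 at adjusted p = 4.6e-10, 9.5e-09 and 4.6e-10. For them, adjusted p = 0.23, 0.23 and 0.23 with an estimated correlation. The stem cell list had a median of -0.09, a mean of 0.05 and 0 called members by edgeR, with 1 higher adjusted over the list alone. LGR5 (-0.60 ± 0.65), ASCL2 (-0.40 ± 0.23), AXIN2 (0.56 ± 0.19), ANXA1 (1.49 ± 0.51), CLU (0.63 ± 0.31) and CTGF (-0.14 ± 0.30) had adjusted p from 0.146 to 0.818. In total 775 genes were higher and 136 lower of 19936 tested. Without CBC replicate 1 or CBC replicate 2 edgeR called 0 genes, the named ones included, with 2741 and 4229 at an unadjusted p under 0.05; without parental replicate 1 it called 2156, and without replicate 2, where EMP1, RPS28 and RPS27 were also lost, 535. DESeq2 called 1970 on all samples.

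Against RSC cells, the summed parental cells held the CBC transcripts SEMA3C (63.9 ± 48.8 against 0.0333 ± 0.0277 CPM) and AC104823.1 (206 ± 36.7 against 0.152 ± 0.190). The sums also held DACH1 (82.9 ± 26.5 against 0.168 ± 0.0736) and KLRC2 (120.2 ± 15.7 against 0.419 ± 0.0804). Higher too were GRIN2B (log2 fold change 9.93 ± 0.45), ASB4 (48.2 ± 7.88 against 0.0949 ± 0.0278 CPM), SPANXD (9.94 ± 0.61), TFF3 (8.69 ± 0.59), and SEMA3A (8.49 ± 0.32). Also higher were PDGFC (8.64 ± 0.40), CDX1 (7.49 ± 0.88), MYB (4.09 ± 0.19) and BMP4 (3.41 ± 0.27). LGR5 was higher at a ratio of 138 (95% counting interval 46.8 to 670.4). Lower were TGM2 (-2.69 ± 0.58), S100A2 (-2.61 ± 0.58), the keratin KRT81 (-2.61 ± 0.36), CRIP1 (-2.56 ± 0.45), IGFBP6 (-2.42 ± 0.43), HOXB8 (-2.16 ± 0.43) and PSMB8 (-1.07 ± 0.16). CTGF was higher (1.43 ± 0.31), AXIN2 (-0.82 ± 0.19) and CLU (-1.18 ± 0.31) were lower, and ANXA1 (0.48 ± 0.50) and ASCL2 (0.06 ± 0.23) were not called (adjusted p = 0.493 and 0.857). Of the regenerative list 8 of 14 and of class I genes 6 of 11 were lower, and 5 of 11 stem cell genes were higher (adjusted over the list alone, 8, 8 and 5). Camera called 8 lists, these 3 at adjusted p = 0.00251, 0.00228 and 0.0141. Respectively, adjusted p = 0.615, 0.615 and 0.615 with an estimated correlation. In total 3311 genes were higher and 2758 lower; the sum of 6069 dropped to 2511 without parental replicate 1, 2047 without RSC replicate 1 and 2810 without RSC replicate 2. The calls of AXIN2 (each of these 3 libraries; adjusted p over the alternatives 4.2e-04 to 0.13), CLU (parental or RSC replicate 1; 0.0015 to 0.13), S100A2 (either RSC replicate; 2.0e-04 to 0.14), TGM2 (RSC replicate 2; 3.5e-05 to 0.14) and HOXB8 (RSC replicate 1; 2.4e-06 to 0.097) ended without those libraries.

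Parental tumors held cells nearer to RSC and cells nearer to CBC. Each human cell of the flank tumors was thinned to 2000 UMIs and scored by whether the orthotopic RSC or CBC profile of 4784 genes fitted it better. In parental replicate 1, 12.2% of 6588 cells lay nearer RSC (95% exact interval 11.4% to 13.03%), and in replicate 2, 40.8% of 7158 cells (39.7% to 42.0%). Of the cells of the 2 CBC tumors, 0.011% and 0.018% lay nearer RSC, and of the cells of the RSC tumors 99.8% in each. In parental replicate 1, 0.182% of the cells lay within 3 log10 units of equal fit, and 0.363% in replicate 2. Between 26 and 119 cells per tumor were too shallow for scoring, and 883 in RSC replicate 1; without thinning the parental shares were 12.3% and 40.7%. These intervals cover counting error only, and the 2 parental tumors differed by more than that error.

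**Figure D3:**
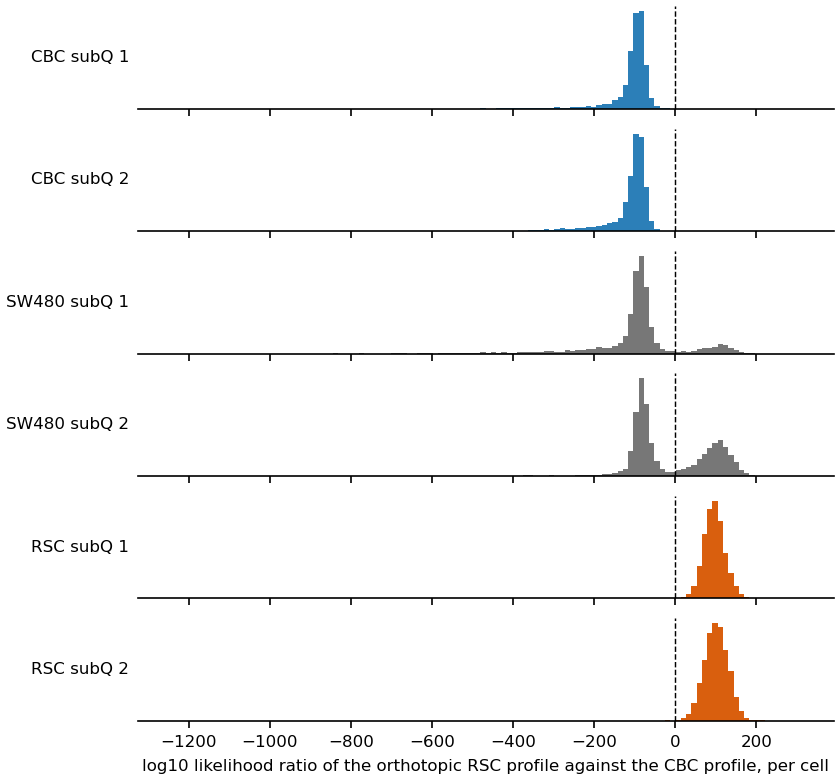
Histograms, 1 per subcutaneous tumor and each scaled to its own height, of the log10 likelihood ratio of the RSC over the CBC profile per human cell. CBC cells lay left of 0 and RSC cells right of 0, and parental tumors held cells on both sides, with 12.2% and 40.8% of them right of 0.

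The mouse cells of the orthotopic samples were mostly epithelial-like, macrophage-like and neutrophil-like (mean share of mouse cells ± SD, n = 4 per group). Epithelial-like cells, led by gut genes such as Zg16, Muc2 and Aqp8, made up 36.0 ± 5.04% in RSC and 39.4 ± 8.10% in CBC samples (exact p = 0.514). This class includes the epithelial clusters whose names are uncertain. Monocyte and macrophage-like cells made up 16.1 ± 2.67% and 18.6 ± 2.99% (p = 0.286 by the exact permutation test), and neutrophil-like cells 13.2 ± 8.17% and 16.5 ± 7.19% (exact p = 0.543). Mast and basophil-like cells, led by Mcpt1, Mcpt4 and Cpa3, were higher in all 4 RSC than in all 4 CBC samples, at 2.19 ± 0.741% and 0.936 ± 0.276%. Dendritic-like cells were lower in all 4 RSC samples, at 0.280 ± 0.0886% and 0.645 ± 0.218%, and the unnamed cluster 5, led by Cd209a, Napsa and Cd7, was higher, at 5.82 ± 0.494% and 4.73 ± 0.499%. For these 3 the exact permutation p was 0.0286, the smallest that 4 against 4 samples can give, and the adjusted p over 12 shares was 0.114, so none passed. The dendritic-like class held 7 to 19 cells per sample, and its direction depended on the clustering. RSC minus CBC was 0.629 points at Leiden resolution 0.5, where a cluster with top genes of cluster 5 took that class. Fibroblast-like cells stood at 12.8 ± 9.07% and 4.47 ± 4.00%, and endothelial-like cells at 3.85 ± 1.70% and 1.60 ± 1.22% (exact p = 0.143 for both). Mural-like cells stood at 2.19 ± 1.43% and 0.940 ± 1.04% (exact p = 0.229), glial-like cells at 0.136 ± 0.0355% and 0.0994 ± 0.136%, and the unnamed cluster 11, led by Il1a, Ccl3 and Csf3, at 3.26 ± 3.08% and 4.58 ± 5.19% (exact p = 0.686 for both). Human cells made up 25.5 ± 13.2% of all assigned cells in RSC and 28.7 ± 10.9% in CBC samples (exact p = 0.686). Shares were taken after a sort for live cells and a limit on mitochondrial UMIs. That limit removed 64.1% to 68.3% of the mouse barcodes of CBC and 39.9% to 64.45% of those of RSC orthotopic samples. At a limit of 50%, chosen after seeing the data, RSC minus CBC moved from -3.41 to -10.7 points for epithelial-like cells. For macrophage-like cells it moved from -2.47 to 1.08 points.

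Subcutaneous tumors held few neutrophil-like cells, 0% to 0.574% of mouse cells, and 0 in both CBC tumors, where 638 and 353 mouse cells were seen. Macrophage-like cells made up 53.3% and 53.3% in CBC, 44.2% and 64.5% in RSC and 49.8% and 65.9% in parental tumors. Fibroblast-like cells made up 26.9% and 28.2% in CBC, 27.6% and 52.0% in RSC and 18.1% and 36.2% in parental tumors. Of this class, 89.2% in CBC, 86.5% in parental and 6.65% in RSC tumors lay in cluster 13, whose name is uncertain, so the CBC and parental shares rest on it. Mural-like cells made up 4.86% and 9.63% in CBC, 1.87% and 3.06% in RSC and 5.74% and 6.95% in parental tumors. With 2 tumors per group no exact test of shares can pass 0.05, and none was made.

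**Figure D4:**
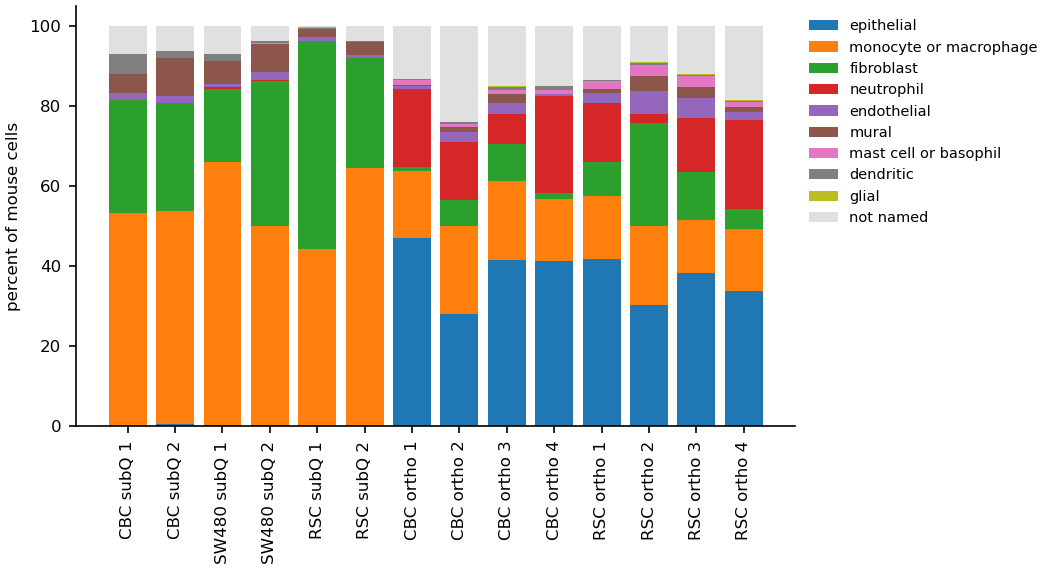
Share of each mouse class among the mouse cells (vertical axis, percent) as stacked bars, 1 bar per sample. Epithelial-like cells, with their clusters of uncertain name, took 27.9% to 47.0% of each orthotopic sample and at most 0.567% of each subcutaneous tumor. In the subcutaneous tumors macrophage-like cells and the fibroblast-like class, with the uncertain cluster 13, led.

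Macrophage-like cells of orthotopic RSC samples held more Spp1 and less Maf than those of CBC samples (mean ± SD of CPM, n = 4 per group). Spp1, osteopontin, stood at 1516 ± 552 against 374 ± 81.1 CPM (log2 fold change 2.02 ± 0.32), and fibronectin, Fn1, rose as well (1.00 ± 0.14). The matrix protein gene Ecm1 rose from 119.6 ± 27.2 to 276 ± 12.3 CPM and Igfbp6 by 1.77 on the log2 scale. Higher too were the placental growth factor Pgf (2.39 ± 0.35), the VEGF receptor Kdr (6.75 ± 2.44 against 2.42 ± 0.293 CPM), the protease Htra1 (2.18 ± 0.33), Olfm1 (1.15 ± 0.21) and the fatty acid binding protein Fabp5 (0.93 ± 0.14). The transcription factor Maf fell from 316 ± 49.7 to 151 ± 29.0 CPM, the scavenger receptor Stab1 from 305 ± 75.7 to 143 ± 29.5 CPM, and the adhesion molecule Vcam1 by 0.70 on the log2 scale. Igfbp4 (-1.20 ± 0.21), the immunoglobulin chain Ighm (-1.02 ± 0.17), the receptor genes Lilra5 (-0.92 ± 0.14) and Klra8 (-0.99 ± 0.16), a family of near-identical members, were lower too. C1qa (0.16 ± 0.13), Cd74 (0.20 ± 0.09) and Ldha (0.41 ± 0.11) were not called (adjusted p = 0.647, 0.33 and 0.0967). Of the lipid-associated list 2 of 11 rose, with a median of -0.11 and a mean of 0.18, and of the endothelial tip list 2 of 8, Kdr and Pgf, rose (camera adjusted p = 0.153 and 0.0985). The inflammatory macrophage list had 0 of 12 members called by edgeR (camera adjusted p = 0.842), the endothelial adhesion list had 1 lower of 4 (0.574), and the cell cycle list 0 of 15 (0.574). Adjusted over the list alone, 4 lipid-associated genes rose and 2 fell, 2 tip genes rose and 1 fell, 1 inflammatory gene rose, 1 adhesion gene fell and 0 cell cycle genes were called. Camera called 5 of 16 lists: collagens and matrix (adjusted p = 0.00127), hypoxia and glycolysis (0.00219) and class II genes (0.0475) higher, and alternative macrophage genes (0.0275) and interferon genes (0.0475) lower. In the same order, adjusted p = 0.601, 0.601, 0.744, 0.601 and 0.601 with an estimated correlation. RNA of other cells was not removed, and the gut gene Cyp2c55, named with the next 4 after their values were seen, was higher in these RSC macrophages too (1.73 on the log2 scale, adjusted p = 0.0231). Aqp8 (2.04), Mcpt1 (1.61), Mcpt2 (1.41) and Car1 (1.35) lay higher without a call, and fibroblast-like cells made up 12.8% of RSC and 4.47% of CBC mouse cells. Endothelial-like cells made up 3.85% of RSC and 1.60% of CBC mouse cells, and Kdr is a marker of that class. Whether the Kdr UMIs came with RNA of endothelial cells was not tested.

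Of 10818 tested genes, 123 were higher and 81 lower in orthotopic RSC macrophages, with most cells of both groups in clusters 3 and 7. The total of 204 dropped to 89 without CBC replicate 1, 111 without CBC replicate 3, 87 without CBC replicate 4, 89 without RSC replicate 1 and 103 without RSC replicate 4. Ecm1, Igfbp6, Maf, Fn1, Fabp5, Ighm, Klra8, Lilra5 and Vcam1 kept their calls without any single library. Calls ended for Spp1 without any library but RSC replicate 3 (adjusted p over the alternatives 3.6e-14 to 0.16), for Stab1 without CBC 1 or 4 or RSC 1, 2 or 4 (1.9e-06 to 0.1). They ended for Pgf without CBC 2, 3 or 4 or RSC 1 (1.3e-14 to 0.1), for Htra1 without CBC 3 or 4 or RSC 1 or 4 (8.3e-13 to 0.16). The call of Igfbp4 ended without CBC 1 or 4 or RSC 1 or 4 (3.1e-07 to 0.088), that of Kdr without CBC 1, 2 or 4 or RSC 4 (2.0e-04 to 0.075) and that of Olfm1 without any of the 4 CBC libraries (2.6e-06 to 0.1).

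Macrophage-like cells of subcutaneous RSC tumors held less Cd209f, Lyve1 and Ccl8 and more Spp1 than those of CBC tumors (mean ± SD of CPM, n = 2 per group). The lectin Cd209f had 0 UMIs in RSC and 518 in CBC tumors and was at least 507-fold lower, and the hyaluronan receptor Lyve1 was lower by a ratio of 458 (95% counting interval 81.1 to 18217). The chemokine Ccl8 fell from 10440 ± 4804 to 491 ± 106 CPM, Cbr2 from 554 ± 87.2 to 27.7 ± 5.24, the growth factor Igf1 from 179 ± 16.9 to 1.73 ± 0.734 with ceruloplasmin, Cp (-5.26 ± 0.39). With the mannose receptor Mrc1 (-2.33 ± 0.29), F13a1 (-2.35 ± 0.30) and Stab1 (-2.30 ± 0.27), 6 of 14 alternative macrophage genes fell. Klra8 (-4.46 ± 0.36), the lipase Lpl (-4.44 ± 0.50), the chemokine Ccl7 (-1.19 ± 0.19) and the interferon gene Ifi27l2a (-2.02 ± 0.31) were lower as well. Spp1 rose from 985 ± 196 to 13403 ± 3148 CPM, Fn1 from 26.4 ± 6.65 to 1672 ± 34.0 and Igfbp6 from 9.79 ± 0.568 to 148 ± 9.57. With them rose Gcnt2 (4.50 ± 0.55), Tspan13 (4.00 ± 0.34), Ecscr (3.62 ± 0.63) and the lysosomal Cd63 (0.68 ± 0.15), and Pgf by a ratio of 38.8 (10.6 to 322). Of 13 hypoxia and glycolysis genes 4 rose, namely Ndrg1 (3.55 ± 0.63), Egln3 (2.48 ± 0.65), Ldha (1.27 ± 0.30) and P4ha1 (0.95 ± 0.20). The complement list had 1 member higher and 1 lower of 11, and the interferon list 1 lower of 14. When adjusted over the list alone, 8 alternative macrophage genes and 6 interferon genes fell, 9 hypoxia genes rose, and 1 complement gene rose and 1 fell.

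Camera called 4 of 15 lists in these macrophages: alternative macrophage (adjusted p = 7.0e-14) and interferon genes (4.1e-07) lower, and hypoxia genes (1.1e-09) and matrix genes (0.0031) higher. In that order, adjusted p = 0.0542, 0.628, 0.628 and 0.628 with an estimated correlation. Of 9575 tested genes 354 were higher and 451 lower, 805 in all, and with the mouse as a block, since the CBC and RSC tumors of 1 number grew on both flanks of 1 mouse, 1408 were called. Different clusters held these cells: 47.9% of CBC macrophages but 0.830% and 0.980% of the macrophages of the RSC tumors lay in cluster 16, and 89.6% of RSC macrophages lay in cluster 1. The total dropped to 420 without CBC replicate 1, 516 without CBC replicate 2 and 504 without RSC replicate 2. Calls of Fn1 (adjusted p over the alternatives 7.4e-37 to 0.13), Pgf (9.4e-15 to 0.26), Ndrg1 (1.6e-05 to 0.26; 0.107 with the block) and Ecscr (1.0e-12 to 0.15) ended without any 1 of the 4 libraries. Those of Cd63 (5.7e-05 to 0.078), Ldha (1.7e-11 to 0.25) and Egln3 (6.1e-05 to 0.41) ended without either CBC library or RSC replicate 1. The call of Cd209f (3.6e-42 to 0.079; 0.0759 with the block) ended without either CBC library or RSC replicate 2. Those of P4ha1 (4.1e-04 to 0.094) ended without either CBC library, and of Ccl8 (1.4e-29 to 0.12) and Ifi27l2a (8.1e-20 to 0.096) without either RSC library. Between the sites, 120 of 9477 macrophage genes tested at both were called at both: 68 higher and 51 lower at both, against 4.1 and 3.5 for independent lists, and 1 with opposite signs.

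**Figure D5:**
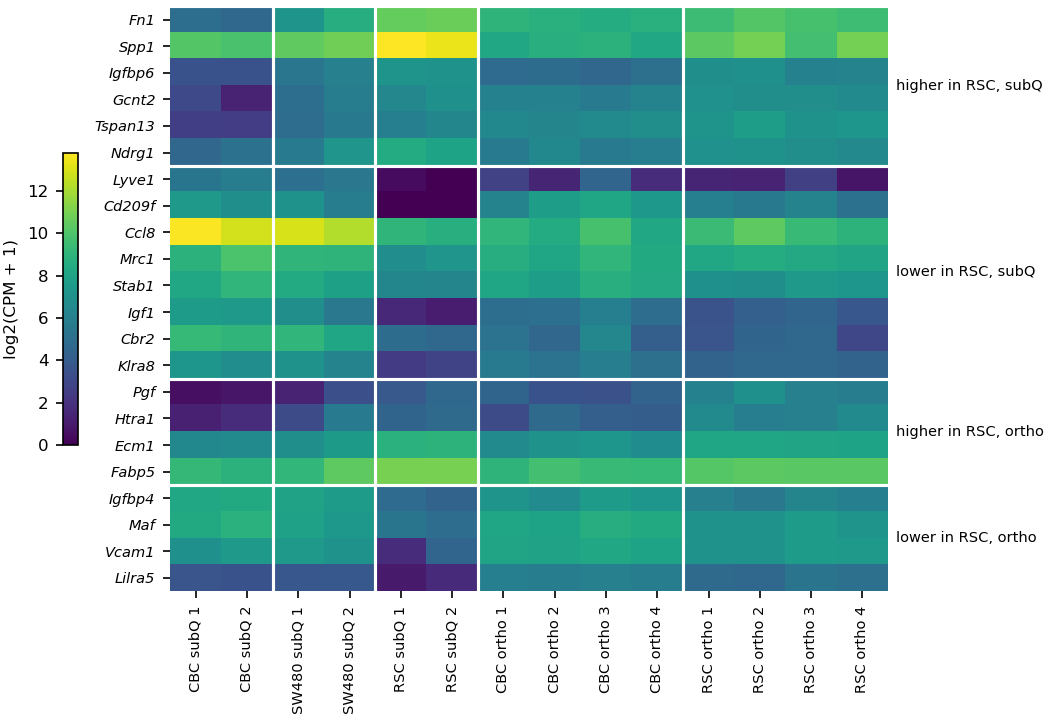
Genes of macrophage-like cells as log2(CPM + 1) of the summed cells without TMM scaling, with 1 column per library and brighter cells higher. Spp1, Fn1 and Igfbp6 were brighter in RSC than in CBC libraries at both sites, and Lyve1 and Cd209f were dark in subcutaneous RSC libraries.

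Fibroblast-like cells of subcutaneous RSC and CBC tumors (mean ± SD of CPM, n = 2 per group) came mostly from different clusters. Cluster 13 held 89.2% of the CBC and cluster 9 held 92.4% of the RSC fibroblasts, and by pooled counts cluster 13 had a glial marker, S100b, and no fibroblast marker among its top genes. The class name of most CBC cells is therefore uncertain, and the differences also lie between clusters. Of 13 contractile fibroblast genes 7 rose, with Lrrc15 (1.94 ± 0.19) and calponin, Cnn1, by a ratio of 50.8 (95% counting interval 13.9 to 421), and 1 fell, Hopx (-3.70 ± 0.50). Of 14 inflammatory fibroblast genes 3 fell, Cxcl12 (-1.13 ± 0.19) and Ly6c1 (-1.58 ± 0.21) among them. The Wnt antagonist Sfrp1 fell from 364 ± 17.8 to 34.0 ± 3.05 CPM, Bmp4 fell (-3.50 ± 0.61) and the ligand Wnt2 rose (2.16 ± 0.22), in a list with 4 genes higher and 4 lower of 16. Of 15 collagen and matrix genes the crosslinking enzyme Lox rose (1.63 ± 0.20) and 3 fell, Col3a1 (-0.80 ± 0.14) among them, without a call of the list (camera adjusted p = 0.497). Comp, a cartilage matrix protein, fell from 279 ± 95.7 to 4.22 ± 0.638 CPM and S100b from 232 ± 46.4 to 5.76 ± 0.370, with Dpt (-4.54 ± 0.60), Apoc1 (-4.22 ± 0.49), Meox2 (-3.38 ± 0.60), the complement gene C4b (-2.44 ± 0.22) and Vcam1 (-2.44 ± 0.22). Of 13 hypoxia and glycolysis genes 10 rose, with the glucose transporter Slc2a1 (2.43 ± 0.30) and Vegfa (2.12 ± 0.36). Macrophage genes led the rising side: C1qa stood at 249.8 ± 104 against 5.07 ± 1.76 CPM. Higher as well were C1qb (4.79 ± 0.39), C1qc (4.61 ± 0.42), Ctss (5.18 ± 0.38), Cd74 (5.14 ± 0.73), Fcer1g (4.56 ± 0.41), Trem2 (4.04 ± 0.66) and Fabp5 (3.02 ± 0.25), and Ccl4 at least 14.7-fold higher. C1qa, C1qb and C1qc together reached 623 and 348 CPM in the 2 RSC fibroblast sums, 2.47% and 1.92% being the median level of macrophage-specific genes there relative to macrophages, and 13.1 and 16.0 CPM in the CBC sums.

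In these fibroblasts camera called 11 of 15 lists, among them contractile (adjusted p = 9.7e-08), hypoxia (1.3e-16), complement (0.00101), class II (4.1e-05), lipid-associated (0.00701) and tumor-conditioned neutrophil genes (1.2e-05) higher, and inflammatory fibroblast (0.00419), Wnt and BMP (0.0346) and interferon genes (3.9e-04) lower. For them, adjusted p = 0.138, 0.181, 0.181, 0.274, 0.181, 0.181, 0.294, 0.274 and 0.388 with an estimated correlation. With calls adjusted over the list alone, 8 contractile genes rose and 2 fell, 4 inflammatory fibroblast genes fell, 5 Wnt and BMP genes rose and 7 fell, 3 matrix genes rose and 5 fell, 13 hypoxia genes rose, 6 complement genes rose and 3 fell, and 2 class II genes rose. Of 10863 tested genes 499 were higher and 417 lower. With fibroblasts that held a C1q UMI removed, a choice made after seeing the data that by itself lowers macrophage genes, 391 genes were higher and 353 lower, 697 of them called before with the same sign, and Ctss, Cd74 and Fcer1g were no longer called.

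The count of 916 dropped to 410 without CBC replicate 1, 573 without CBC replicate 2 and 521 without RSC replicate 2. Calls ended for Meox2 without any 1 of the 4 libraries (adjusted p over the alternatives 1.4e-10 to 0.31; 0.179 with the mouse as a block) and for Bmp4 without CBC replicate 1 or either RSC library (5.1e-14 to 0.11). Calls of Dpt (1.2e-22 to 0.098) and S100b (7.5e-31 to 0.096; 0.0556 with the block) ended without either RSC library, and of Cd74 (4.7e-31 to 0.57) without either CBC library. Trem2 (5.1e-17 to 0.058) and Vegfa (4.8e-19 to 0.086) lost theirs without CBC replicate 1, and Apoc1 (1.2e-41 to 0.053) and Col3a1 (1.3e-05 to 0.095) without RSC replicate 2.

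Fibroblast-like cells of the orthotopic samples gave 5 called genes of 10758 tested by edgeR, each higher in RSC samples, from 3 CBC samples and 4 RSC samples with at least 20 such cells. Epha3, an ephrin receptor, stood at 59.6 ± 17.9 against 1.37 ± 1.22 CPM (mean ± SD), and the immediate-early gene Fos at 1729 ± 154 against 946 ± 74.4 CPM. The others, named after their values were seen, were the mast cell proteases Mcpt1 (9.33 ± 0.84) and Mcpt2 (5.02 ± 0.59), genes of another cell type, and the hormone-like Pthlh (3.91 ± 0.49). Acta2, smooth muscle actin (-1.19 ± 0.72, adjusted p = 0.754), Postn (-0.95 ± 0.23, 0.376) and Sparc (-0.58 ± 0.14, 0.29) were not called. Contractile and matrix genes had 0 called members of 11 and 15, and camera, which called 9 of 16 lists, placed both lower (adjusted p = 0.0209 and 1.3e-08), with the cell cycle list (1.3e-08), and the endothelial tip list (6.9e-04). It placed higher the stress list with Fos (3.9e-07) and 4 lists of other cell types: tumor-conditioned neutrophil (2.5e-08; median 1.60), inflammatory macrophage (3.5e-06; median 1.64), endothelial adhesion (0.0132) and class II genes (0.0392). Respectively, adjusted p = 0.545, 0.165, 0.206, 0.189, 0.189, 0.189, 0.189, 0.189 and 0.559 with an estimated correlation. Adjusted over the list alone, 1 contractile, 8 matrix and 1 tip gene were lower, 0 cell cycle genes were called, and 4 stress and 2 adhesion genes were higher. At an unadjusted p under 0.05 there were 837 genes, and DESeq2 called 71, of which 63.4% were higher against 100% by edgeR. The count was 0 without CBC replicate 2 or 3 or RSC replicate 2 or 3, 1 without RSC replicate 1 or 4 and 9 without CBC replicate 4. Fos (adjusted p over the alternatives 4.5e-08 to 0.27) lost its call without any 1 of the 7 libraries, Mcpt1 (5.0e-06 to 0.39), Mcpt2 (4.9e-04 to 0.33) and Pthlh (0.0032 to 0.36) without any but CBC replicate 4, and Epha3 (1.3e-12 to 0.23) without CBC replicate 2 or 3 or RSC replicate 2 or 3. Cluster 14 held 32.0% of RSC and 6.10% of CBC fibroblasts, and cluster 9 held 3.33% and 15.3%.

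Neutrophil-like cells of the orthotopic samples (mean ± SD of CPM, n = 4 per group) had 20 higher genes in RSC samples, mostly those of other cell types. The mast cell protease Mcpt2 stood at 52.8 ± 15.7 against 1.87 ± 1.53 CPM, and carbonic anhydrase, Car1, a gut epithelial gene, at 411 ± 182 against 84.8 ± 22.7. Of the same kind, Fabp2 stood at 79.4 ± 23.1 against 31.4 ± 5.46, Dmbt1 at 124 ± 31.1 against 47.2 ± 20.0 and Pigr at 62.7 ± 18.0 against 29.5 ± 10.1 CPM. C1qa rose too (1.61 ± 0.32), and the neutrophil gene Stfa2l1, of a family of near-identical copies, fell from 1266 ± 85.1 to 817 ± 151 CPM. Of the 20 higher genes, 18 were at least 10-fold higher in another mouse class, 14 of them in epithelial-like cells. The immature neutrophil list had 0 called members of 8 and the tumor-conditioned list 0 of 13 by edgeR (camera adjusted p = 0.123 and 0.525), with Cxcl2 at 0.16 ± 0.14. When adjusted over the list alone, 2 immature neutrophil genes were lower and 1 complement and 1 class II gene higher. Camera placed the complement (1 called member of 6, adjusted p = 0.0214) and class II lists (0 of 4, 6.2e-04) higher, and adjusted p = 0.265 and 0.265 with an estimated correlation. The total of 21 of 4465 tested genes dropped to 5 without CBC replicate 1, 7 without CBC replicate 4 and 11 without RSC replicate 1, and was 94 without RSC replicate 4. Calls ended for Stfa2l1 without any library but RSC replicate 3 (adjusted p over the alternatives 0.0098 to 0.24), for C1qa without CBC 1, 3 or 4 or RSC 1 or 3 (3.3e-06 to 0.16). They ended too for Pigr without CBC 1 or 4 or RSC 1 (1.6e-04 to 0.1), for Dmbt1 without CBC 1 or 4 (1.4e-06 to 0.054) and for Car1 without CBC 1 (4.1e-30 to 0.053). Endothelial-like cells were not compared, since only 2 orthotopic CBC samples and 0 subcutaneous CBC or RSC tumors held 20 of them, and neutrophil-like cells were not compared under the skin, where 0 CBC or RSC tumors held 20.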

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

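Of the tests in this part, the ones on the scatter of single genes along chromosomes, on expression by fibroblasts and on the UMIs of fibroblasts with C1q were chosen after the result was seen.

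Macrophage genes such as C1qa were higher in fibroblast sums of subcutaneous RSC than CBC tumors. Free RNA spread evenly over droplets is argued against, since the top 10% of fibroblasts held 89.4% of the C1q UMIs in RSC replicate 1 and 98.1% in replicate 2, against at most 34.3% and 24.1% in 1000 even draws. Macrophage RNA may have come in whole, with macrophages or joined droplets, since 81.3% and 82.9% of the macrophage-specific genes lay within 2-fold of 1 common ratio to macrophages. Expression of these genes by the fibroblasts themselves is argued against by the same 81.3% and 82.9%, since genes switched on singly would differ in that ratio. The genes were chosen as far lower in fibroblasts than in macrophages of the orthotopic samples. That choice left out genes that fibroblasts commonly express, and it may have narrowed the ratio under the skin beforehand. For other genes the ratio decides nothing. Whether macrophages among the fibroblasts or joined droplets brought the RNA stays open: fibroblasts with C1q held a median of 2994 UMIs against 8803 without it in replicate 1, where 24.3% of the barcodes mixed both species, and 16262 against 15164 in replicate 2.

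Genes of gut epithelium and mast cells, such as Car1, Fabp2 and Mcpt2, were higher in neutrophil-like cells of orthotopic RSC samples. RNA of other cells in the droplets could account for them, since 11 of the 12 (91.7%) that macrophages also lack had a log2 fold change above 0 in RSC macrophages, Cyp2c55 and Pigr with a call and the other 9 without. All of the genes, 100%, lay within 2-fold of 1 common ratio to all mouse cells. That cannot decide on expression by the neutrophils, since the genes were chosen as at least 10-fold below another class. They also had to pass the filter on low counts, so the ratio was narrowed beforehand. Whether the neutrophils expressed some of them stays open, as does why RNA of other cells would have reached RSC droplets more.

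Neighbouring genes shared their difference between RSC and CBC human cells over long stretches of chromosomes. Scatter of single genes is argued against by the SD of the medians of 151 windows of 20 Mb, 0.353 log2 units against at most 0.207 in 1000 shuffles. Bias of single libraries is argued against too, since the same windows differed between RSC-like and CBC-like cells inside each parental tumor (correlations 0.945 and 0.958 across windows). A difference in DNA copy number may account for it, with a correlation of 0.791 between windows of low and of high expressed genes. DNA was not measured, so copy number itself stays open.

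Samples were also split in other ways with group sizes kept, and the real split is counted in each number here. For human cells in the cecum 1 of 35 splits, the real one, gave as many genes as the labels (10891, highest other 0). It was the real one alone too for orthotopic macrophages (1 of 35; 204, highest other 13), neutrophils (1 of 35; 21, highest other 17) and the site comparison (1 of 100, drawn within each line; 7520, highest other 2565). For orthotopic fibroblasts 3 of 35 splits gave at least 5 genes, the real one and 2 others, the highest with 15.

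A sample lay far from the other 3 of its group in 10 of 192 groups of values, where about 1 in 20 would by chance. Among CBC orthotopic samples these were cluster 11 in replicate 2 (12.3% of mouse cells), IFITM1 in replicate 3 (0.0371 CPM), TGM2 in replicate 2 (4.64 CPM), C3 in replicate 1 (0.0918 CPM) and HLA-B in replicate 4 (24.0 CPM). Among RSC orthotopic samples they were SEMA3D (0.0789 CPM), DWORF (0.8285 CPM) and LGR5 (0.0395 CPM) in replicate 1, and IFI27 (100.1 CPM) and macrophage Olfm1 (178.1 CPM) in replicate 2. IFITM1, C3 and LGR5 gave 1 UMI in that whole group and SEMA3D 2, with the other samples at 0 CPM. These values lie at the floor, where 1 UMI alone sets a sample far apart and the rate of 1 in 20 does not hold.

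The difference between RSC and CBC differed between the sites for 1630 genes. By log2 units it was lower in the cecum for MSLN (-2.39), ITGB4 (-1.86), AJUBA (-2.32), F3 (-1.84), TM4SF1 (-2.04), LATS2 (-2.25), PTPN14 (-1.18), ANXA1 (-4.48), EMP1 (-3.84), IL18 (-4.99), RRM2 (-0.98), VIM (-1.23) and BIRC5 (-0.99). It was higher for B2M (1.23), BST2 (1.81), CDX2 (1.31), CSF1 (2.47), MMP9 (4.16), NOTUM (1.51), TNFRSF19 (1.13), RNF43 (1.00) and CFB (2.86).

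Among barcodes left out, 24.3% of those of RSC subcutaneous replicate 1 mixed both species, against at most 1.33% in parental tumors. In CBC orthotopic replicate 1, 68.3% of the mouse barcodes were over the mitochondrial limit, against at most 6.22% in parental tumors and 39.9% to 66.5% in the other orthotopic samples. In RSC orthotopic replicate 1, 63.3% of the human barcodes were, against at most 13.2% in parental tumors and 25.2% to 52.4% in the other orthotopic samples, so high shares go with the site and not with these samples alone.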

How the results depend on the processing

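The tests on fibroblasts without C1q UMIs, on a mitochondrial limit of 50% and on cells not thinned were chosen after the result was seen. The counts of called genes between human RSC and CBC cells stayed within 1.5 times in the alternatives run, at 9635 to 12690 genes in the cecum and 6891 to 11123 under the skin, as did that of orthotopic against subcutaneous cells, at 5629 to 7854. Single calls were lost: 9310 (mitochondrial limit of 10%) to 10838 of the 10891 in the cecum, 6628 (without RSC replicate 2) to 9851 of the 9889 under the skin and 5481 (without RSC subcutaneous replicate 1) to 7439 of the 7520 between the sites were called again. Of 4863 alternative values for 290 named gene values, 4575 stayed on their side of the threshold, 256 lost their call, 15 gained one and 17 changed sign. RLE size factors changed no call of these named values. Depth limits genes near 0 UMIs, and 2 tumors per group limit the subcutaneous mouse classes. The cause of the changes below was not tested, except that leaving out a library leaves fewer samples.

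Parental against CBC cells, 911 genes, gave 1970 by DESeq2, 1507 without the filter, 2364 in a fit over both sites, 1383 with the replicate number as a block and 457 at a mitochondrial limit of 10%, and 0 to 2156 without 1 library. Parental against RSC cells, 6069 genes, gave 2047 to 6031 without 1 library. The interaction of site and line, 1630 genes, gave 926 to 1734 without 1 library and 1245 (a fit over both sites) to 2318 (without the filter) in the others. Orthotopic fibroblasts, 5 genes, gave 71 by DESeq2, 30 without the filter, 17 over both sites, 3 with the number as a block, 3 at a mitochondrial limit of 10%, 3 at Leiden resolution 0.5, 1 at resolution 2.0, 3 after Scrublet removal and 0 to 9 without 1 library. Subcutaneous fibroblasts, 916 genes, gave 1559 without the filter, 744 without C1q UMIs, 1266 with the mouse as a block and 410 to 890 without 1 library. Orthotopic macrophages, 204 genes, gave 337 by DESeq2, 406 without the filter and 87 to 281 without 1 library. Subcutaneous macrophages, 805 genes, gave 1402 without the filter, 1371 over both sites, 1408 with the mouse as a block and 420 to 688 without 1 library. Neutrophils, 21 genes, gave 102 without the filter, 54 with the number as a block and 5 to 94 without 1 library. Of the 83 lists that camera called at its preset correlation, 0 were called with an estimated correlation, and over all lists fry called 47.

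With the mouse as a block, the human subcutaneous count was 11123, and apart from the calls named in the report the block changed no other gene call named there. Orthotopic samples share only a number, as do parental tumors and the others. With it as a block, the counts were 11126 for human cells in the cecum, 6780 for parental against RSC cells, 1785 for the interaction, 6179 for the site comparison and 172 for orthotopic macrophages. Same-numbered samples correlated at 0.0209 to 0.0532 in the cecum, where none correlated best with its own number, at -0.126 between CBC and parental and at 0.170 between RSC and parental tumors. No paired analysis was possible for the tests of orthotopic shares, because those samples share only a number. Subcutaneous shares were not tested, but in both mice the RSC tumor held fewer mural-like (1.87% against 4.86%, and 3.06% against 9.63%), dendritic-like (0.288% against 4.86%, and 0.333% against 1.70%) and endothelial-like cells than the CBC tumor. Cluster 5 and the human share were lower too and fibroblasts higher, and macrophages went both ways.

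RSC minus CBC shares changed sign for dendritic-like cells at Leiden resolution 0.5 (0.629 points), where a cluster with top genes of cluster 5 (Cd209a, Napsa) took that class, and for macrophages at a mitochondrial limit of 50% (1.08 points). Without 1 library the human share ranged from -9.73 to 1.54 points (above 0 without CBC replicate 3), neutrophils from -6.41 to 0.212 (without RSC replicate 2) and cluster 11 from -2.74 to 1.24 (without CBC replicate 2). Other differences moved by over 1.5 times without a change of sign: epithelial cells from -3.41 to -10.7 points at the limit of 50%, -7.25 without CBC replicate 2, -5.33 without RSC replicate 1, -2.22 at the limit of 10%, -1.51 without RSC replicate 2 and -0.910 without CBC replicate 1. The human share went from -3.24 to -10.02 points at the limit of 10%, -0.505 at 50% and -1.79 at a species limit of 90%, and fibroblasts from 8.29 to 4.00 without RSC replicate 2. Neutrophils went from -3.35 to -0.101 points at the limit of 50%, -5.22 at 10% and -6.95 among non-epithelial mouse cells, and mural-like cells from 1.25 to 0.687 without RSC replicate 2. Macrophages went from -2.47 to -1.27 points without CBC replicate 2, -1.52 without RSC replicate 3, -3.96 at the limit of 10% and -5.56 among non-epithelial mouse cells, and dendritic-like cells from -0.364 to -0.226 at the limit of 50% and -0.648 among non-epithelial cells. Over all alternatives, with shares among non-epithelial mouse cells included, fibroblasts ranged up to 12.4 points, endothelial cells from 1.68 to 3.41, mast cells from 1.06 to 1.84 and glial cells from 0.00328 to 0.103. The lowest adjusted p of any share was 0.114. Cells nearer RSC made up 99.6% of RSC replicate 2 without a fold minimum and 0% of CBC replicate 2 when not thinned. The other position shares stayed within their ranges, with 12.2% to 12.4% and 40.5% to 40.8% in parental tumors.

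Log2 fold changes that changed sign were all uncalled. ASCL2 in the cecum stood at 0.0005099 without the filter and at -0.10 to 0.0515 without 1 library, and against RSC in parental cells at -0.0119 over both sites and -0.21 to 0.41. CLU between the sites stood at -0.0218 without the filter and -0.0915 to 0.22 without 1 library. LGR5 in the interaction stood at 0.10 at a species limit of 90% and -2.81 to 2.24 without 1 library, between the sites at -1.45 to 1.11 and in parental against CBC cells at -1.84 to 0.0775. CTGF in the interaction ranged from -0.88 to 0.22 and ANXA1 in parental against RSC cells from -0.0378 to 1.15.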

Other observations

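The values on chromosomes come from the tests described above, of which 1 was chosen after the result was seen.

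Human genes of chromosomes 13, 17, 3 and 9 were mostly higher in RSC than CBC cells, with median log2 fold changes of 0.60, 0.55, 0.51 and 0.48 in the cecum and 0.54, 0.47, 0.41 and 0.42 under the skin. Genes of chromosomes 18, 19 and 15 were mostly lower, at -0.46, -0.36 and -0.33 in the cecum and -0.50, -0.42 and -0.51 under the skin. Across windows, which are not independent replicates, the sites correlated at 0.952, and the windows held 10.7% of the variance of single genes against 2.18% after shuffling. Gain or loss of whole chromosome parts in 1 of the lines may underlie this, given the SD of 0.353 between windows, but it was not measured.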
